A study of Danio rerio with 6 samples.

How the data were processed

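Gene expression was measured by RNA sequencing in 6 zebrafish libraries, 3 from embryos exposed to BP-3 at 2 mg/L and 3 from controls, sampled at 5 days after fertilization. Per the labels' protocols, intestinal tissue was dissected, total RNA was extracted with TRIzol and libraries were sequenced in paired-end mode on an Illumina HiSeq instrument. The authors deposited 1 table per library of raw read counts per gene, with no normalization. The aligner, the counting tool, the annotation and the use of strand are not given in the sources used here, and reads from overlapping or antisense genes cannot be told apart. Per the submitters' processing notes the genome build was mm9, a mouse build, whereas 21639 of the 32053 row names are zebrafish symbols of the reference table, so no coordinates are given.

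Each deposited count table held 32053 rows under 28715 distinct names. Of these names, 586 stood on more than 1 row (3924 rows), and for them list members were taken from the row with the highest total. A further 19 rows carried names that read as dates, of which 1 passed the threshold, and 2746 rows were RNA families. No row had a blank name. Library sizes in the fits were taken over the rows kept by the filter, while shares of counts used all rows. Among low counts, rows at 4 were more frequent than rows at 3 in all 6 libraries (335 against 328 in BP-3 replicate 1, and 407 against 319 in BP-3 replicate 2), a pattern that counting both mates of a read pair would give. Total counts lay between 23567603 and 41726516. Counts of copies made by PCR are not independent molecules, so intervals and floors cover counting error only.

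Libraries were grouped by their titles. The treatment field of the exposed libraries reads BP-3, BP-4 and BP-5 while the protocol names 1 compound, so the fit with BP-3 replicate 1 alone was made as an alternative. Rows were filtered with filterByExpr, which left 23167 and removed 8886, and libraries were scaled with TMM. Groups were compared with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest) without covariates, and p-values were adjusted by Benjamini-Hochberg over all rows, with a threshold of 0.05. Fold changes are BP-3 over control. For the count of larger changes an absolute log2 fold change of at least 1 was required. CPM values, counts relative to library size, are scaled by the TMM factors and given as mean ± SD of 3 libraries.

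A total of 43 gene lists was written before the data were examined: responses to a xenobiotic compound, markers of gut cell types and of neighbouring tissues, and lists of RNA quality. The files held 1655 of the 1747 genes written. All 43 lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, with its preset correlation of 0.01 and with an estimated correlation, and with fry. Benjamini-Hochberg adjustment ran over the lists. By camera 22 lists passed, 16 up and 6 down, and 0 passed with an estimated correlation, where 12 had an unadjusted p under 0.05. In that setting camera also takes its degrees of freedom from the few libraries, which raises p whatever the correlation. For sterol synthesis the estimated correlation was -0.008, below the preset, yet the unadjusted camera p rose from 8.28e-13 to 0.00132. By fry 26 lists moved on balance in 1 direction and 41 in either. Enteric nervous system, goblet cell, inflammation, glucocorticoid response, retinoic acid response and histones passed fry in 1 direction and not camera. Exocrine pancreas and mitochondrially encoded genes passed camera and not fry in 1 direction. Of 1531 distinct list members tested, 384 passed over all genes, 251 higher and 133 lower.

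Genes named in the text were chosen by a rule fixed before the data were examined. It took the 10 largest increases and the 10 largest decreases among genes past the threshold with a mean log2 CPM of at least 1, groups that do not overlap and a symbol that is not a clone name. It also took up to 4 members of each list with the smallest adjusted p, and a panel of 14 genes whatever their values. Named outside the rule, after their values were seen, are egr1, hspa8, and the genes so marked.

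Before use, the gene test was tested on 5 simulated data sets of the 23167 genes with 200 changed genes each. It called 53.4% of genes changed 1.5-fold, 89.0% of those changed 2-fold and 100% of those changed 4-fold, and 8.9% of its calls fell on unchanged genes, above the nominal share. The median error of the log2 fold change was 0.095. The alternatives were other scaling (DESeq2 size factors and upper quartile), other filters (none, and 1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out, and BP-3 replicate 1 alone. With both replicate 3 libraries left out, and with them as a batch term, 2 alternatives were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. With 3 against 3 libraries, an exact permutation test cannot give p below 0.1.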

Results

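RNA was sequenced from zebrafish at 5 days after fertilization, from tissue that the labels call intestinal and that was dissected with forceps. Exposed embryos were kept in 2 mg/L of BP-3; the abbreviation is in common use for the ultraviolet filter benzophenone-3, which the labels do not spell out. The other embryos are labelled control. Each of the 2 groups had 3 libraries. Total counts were 41726516, 34944023 and 24000785 in BP-3 replicates 1 to 3 and 36961866, 29123853 and 23567603 in control replicates 1 to 3. The labels do not say whether replicates came from separate clutches or pools of embryos, so the p-values measure the spread between these libraries only. In the treatment field the 3 exposed libraries read BP-3, BP-4 and BP-5, while their titles and the protocol name BP-3 alone, and they were taken as 1 group.

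The comparison of exposed with control libraries asks which transcripts differed after exposure to BP-3. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2446 of 23167 tested rows passed an adjusted p of 0.05, of which 1451 were higher and 995 lower in the BP-3 group. Most changes were small, with a median of 1.4-fold among the called genes, and 251 genes changed at least 2-fold, 173 of them upward and 78 downward. In 31.0% of tested rows the 3 values of each group did not overlap, where chance gives 10%. Of 43 gene lists written before the data were examined, 22 passed camera with its preset correlation, 16 up and 6 down. With an estimated correlation 0 passed, but that setting also takes its degrees of freedom from the 6 libraries alone. A pass lost there need not mean that the members of a list move together. The smallest adjusted p upward was that of sterol synthesis, with 15 of 26 genes higher (1.78e-11, and adjusted p = 0.0568 with an estimated correlation). Downward it was that of immediate early genes, which respond to stimulation within minutes, with 21 of 42 lower (3.04e-14, and adjusted p = 0.0990 with an estimated correlation).

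Among the 10 largest increases that met the rule for named genes and had counts in both groups, hsp70.3, an inducible chaperone gene, came first with a rise of 8.90-fold. It lay at 56.8 ± 2.46 CPM (counts scaled to library size) in BP-3 and 6.39 ± 0.831 CPM in control (SD, n = 3). Its relatives hsp70.1, hsp70.2 and hsp70l rose by 5.99-fold, 5.93-fold and 5.25-fold, but these genes are nearly identical copies, so the split of reads among them is uncertain. The cytochrome P450 genes cyp2k6 and cyp2k18 rose by 6.89-fold and 4.01-fold, and they belong to a family of close copies too. The fin fold gene and1, which encodes actinodin of the fin's fibres, rose from 142 ± 4.71 to 605 ± 20.4 CPM (SD, n = 3). Increases were also found for eevs, an enzyme of gadusol synthesis, at 4.12-fold, and for the taste receptor gene tas1r3 at 3.08-fold. The protocadherin gene pcdh2ac had 0 counts in all control libraries and 579 in the BP-3 libraries together, at least 171-fold higher when the control group is set at a floor of 3 counts over the group. If both mates of each read pair were counted, this bound would be lower. It was 1 of 3 called genes with no count in 1 group. The others, si:ch211-236g6.1 and si:dkeyp-51b9.3, had 0 counts in control and 40 and 84 in the BP-3 libraries together. Why these genes had no control counts was not tested.

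Among the 10 largest decreases that met the same rule, npas4a came first encoding an activity-dependent transcription factor, and went from 47.1 ± 4.36 to 5.27 ± 0.10 CPM (SD, n = 3), 8.94-fold lower. The transcription factor gene fosab was 7.52-fold lower and egr4 4.90-fold lower. Expression of btg2, an antiproliferative gene, was 3.75-fold lower, and that of socs3a, a feedback inhibitor of cytokine signalling, was 3.04-fold lower. The iron hormone gene hamp was 4.69-fold lower, and scpp9, a secretory calcium-binding phosphoprotein gene, was 5.73-fold lower. Decreases were also found for ppp1r27b at 4.03-fold, asb15b at 3.68-fold and rtn4rl2a at 3.49-fold. The adjusted p-values of these 20 genes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment lay between 1.87e-07 and 0.00307.

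**Figure D1:**
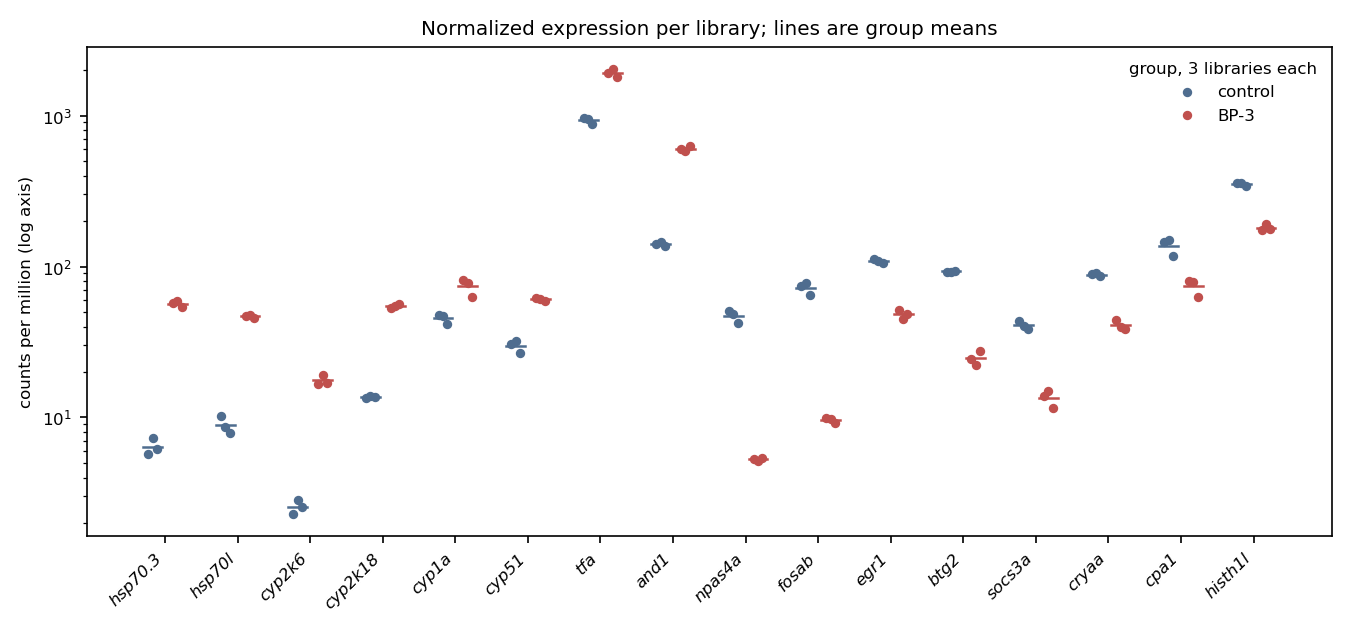
CPM values of 16 genes (log axis) in the 3 control and 3 BP-3 libraries, 1 point per library with lines at the group means. The libraries of the groups do not overlap for any of these genes, which the naming rule required of those among the largest changes. Of the genes shown, hsp70.3 lies at 56.8 CPM in BP-3 and 6.39 in control, and npas4a at 5.27 and 47.1.

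Many genes of xenobiotic metabolism rose. Of 74 members of the phase I and II list, 35 rose and 2 fell (42 and 4 adjusted over the list alone), with a median log2 fold change of 0.28. Examples are the glutathione transferase gene mgst3b at 1.61-fold and the glucuronosyltransferase gene ugt1a2 at 1.57-fold. In the camera test with its preset correlation the list passed (adjusted p = 1.05e-08), and it did not with an estimated correlation (adjusted p = 0.165). Of 40 genes of oxidative stress and Nrf2, 13 rose and 0 fell (20 and 0 adjusted over the list alone; camera adjusted p = 1.27e-07, and adjusted p = 0.270 with an estimated correlation). Among those that rose were txnrd3 at 1.47-fold, gsr at 1.4-fold and prdx1 at 1.75-fold. The 17 targets of the aryl hydrocarbon receptor moved both ways, with 4 higher and 2 lower (6 and 3 adjusted over the list alone; camera adjusted p = 0.277). Among them cyp1a rose from 45.4 ± 3.22 to 74.0 ± 9.71 CPM (SD, n = 3), and foxq1a was 2.43-fold lower. The receptor's repressor gene ahrra had a log2 fold change of -0.11 ± 0.44 (SE) and cyp1b1 one of 0.48 ± 0.16 (SE), neither past the threshold. The cytochrome P450 gene cyp3a65, expressed in liver and gut, was 1.24-fold lower, and nqo1 rose by 1.24-fold; cyp1c1 was not analysed here.

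Of 26 sterol synthesis genes, 15 rose and 0 fell (22 and 0 adjusted over the list alone), with a median log2 fold change of 0.63; cyp51 rose 2.03-fold, mvda 2.24-fold, hmgcs1 1.86-fold and msmo1 1.80-fold. The list passed camera with its preset correlation (adjusted p = 1.78e-11), and not with an estimated correlation (adjusted p = 0.0568). Of 59 genes of fatty acid synthesis and oxidation, 19 rose and 4 fell (27 and 5 adjusted over the list alone; camera adjusted p = 0.000134, and adjusted p = 0.213 with an estimated correlation). The carnitine transferase gene cpt1ab rose 1.46-fold and the uncoupling protein gene ucp2 1.90-fold. Of 17 genes of bile acid handling, 9 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 0.000226, and adjusted p = 0.213 with an estimated correlation). The transporter genes slc51a and abcb11a rose 1.84-fold and 1.98-fold. The receptor gene nr0b2b rose from 0.161 ± 0.0391 to 1.64 ± 0.0720 CPM (SD, n = 3). Of 42 anterior enterocyte genes, 20 rose and 2 fell (25 and 2 adjusted over the list alone). They include the retinol-binding gene rbp2b at 1.99-fold, scarb1 at 1.92-fold and the gluconeogenic gene pck1 at 2.00-fold. The fatty acid binding gene fabp2 lay at 953 ± 98.1 CPM in BP-3 and 792 ± 88.4 CPM in control (SD, n = 3), a difference not past the threshold. In replicates 1 to 3 it lay at 1000, 1018 and 840 CPM in BP-3 and at 858, 827 and 692 CPM in control. The anterior enterocyte list passed camera (adjusted p = 1.05e-08) and had adjusted p = 0.150 with an estimated correlation.

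Of 60 hepatocyte genes, 31 rose and 4 fell (37 and 4 adjusted over the list alone), with a median log2 fold change of 0.37 (camera adjusted p = 7.62e-11, and adjusted p = 0.165 with an estimated correlation). The transferrin gene tfa rose from 928 ± 44.6 to 1918 ± 111 CPM (SD, n = 3), the complement gene c3a.2 by 1.80-fold and the antithrombin gene serpinc1 by 1.6-fold. Among the hepatocyte genes that fell were ahsg1 by 0.82, igfbp1a by 0.47 and fetub by 0.28 on the log2 scale, and these 3 were chosen after their values were seen. Of 20 erythrocyte genes, 11 rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 1.41e-07, and adjusted p = 0.178 with an estimated correlation). The haem synthesis gene alas2 rose 1.78-fold and the embryonic globin gene hbae3 1.66-fold.

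Of 33 heat shock genes, 14 rose and 1 fell (18 and 2 adjusted over the list alone; camera adjusted p = 2.43e-09, and adjusted p = 0.133 with an estimated correlation). The constitutive chaperone gene hspa8 had a log2 fold change of 0.06 ± 0.08 (SE), not past the threshold. Of 46 genes of the unfolded protein response of the endoplasmic reticulum, 16 rose and 1 fell (19 and 2 adjusted over the list alone; camera adjusted p = 2.31e-07, and adjusted p = 0.150 with an estimated correlation). The chaperone genes hyou1 and hsp90b1 rose 1.61-fold and 1.51-fold, and manf 1.91-fold. Among 46 hypoxia genes 8 rose and 3 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.0438, and adjusted p = 0.321 with an estimated correlation). Camera's pass was lost without a count filter (adjusted p = 0.0561), with the replicate block (0.0568), with the replicate 3 batch term (0.0504) and with both replicate 3 libraries left out (0.0697). It was also lost with BP-3 replicate 1 alone (0.0759), without that library (0.0759), without BP-3 replicate 2 (0.0709) and without control replicate 3 (0.0972). In it, hif1al and the glycolytic gene ldha rose 1.72-fold and 1.53-fold, and bnip3 was 1.70-fold lower. The p53 and apoptosis list of 47 held 4 that rose and 10 that fell (8 and 12 adjusted over the list alone), with bbc3 1.70-fold and gadd45ba 2.48-fold lower. Its median log2 fold change of 0.04 and its test direction, down, differ in sign (camera adjusted p = 0.447).

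Of 42 immediate early genes, 0 rose and 21 fell (0 and 26 adjusted over the list alone), with a median log2 fold change of -0.33; egr1 was 2.25-fold and dusp1 2.29-fold lower. The list passed camera with its preset correlation (adjusted p = 3.04e-14) and not with an estimated correlation (adjusted p = 0.0990). Of 32 inflammation genes 3 rose and 8 fell (3 and 10 adjusted over the list alone), with the cyclooxygenase gene ptgs2b 2.61-fold lower. For inflammation camera gave adjusted p = 0.0813 and fry adjusted p = 0.0171. The glucocorticoid list of 29 moved both ways, with 5 higher and 6 lower (6 and 7 adjusted over the list alone). In it fkbp5 rose 2.49-fold, while cebpd was 1.79-fold lower. For this list camera gave adjusted p = 0.248 and fry adjusted p = 0.0164. Of 45 circadian clock genes 3 rose and 10 fell (5 and 15 adjusted over the list alone; camera adjusted p = 0.00303, and adjusted p = 0.293 with an estimated correlation), with nfil3-5 1.94-fold and nr1d4b 2.1-fold lower. Of 29 interferon genes 2 rose and 2 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.157).

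**Figure D2:**
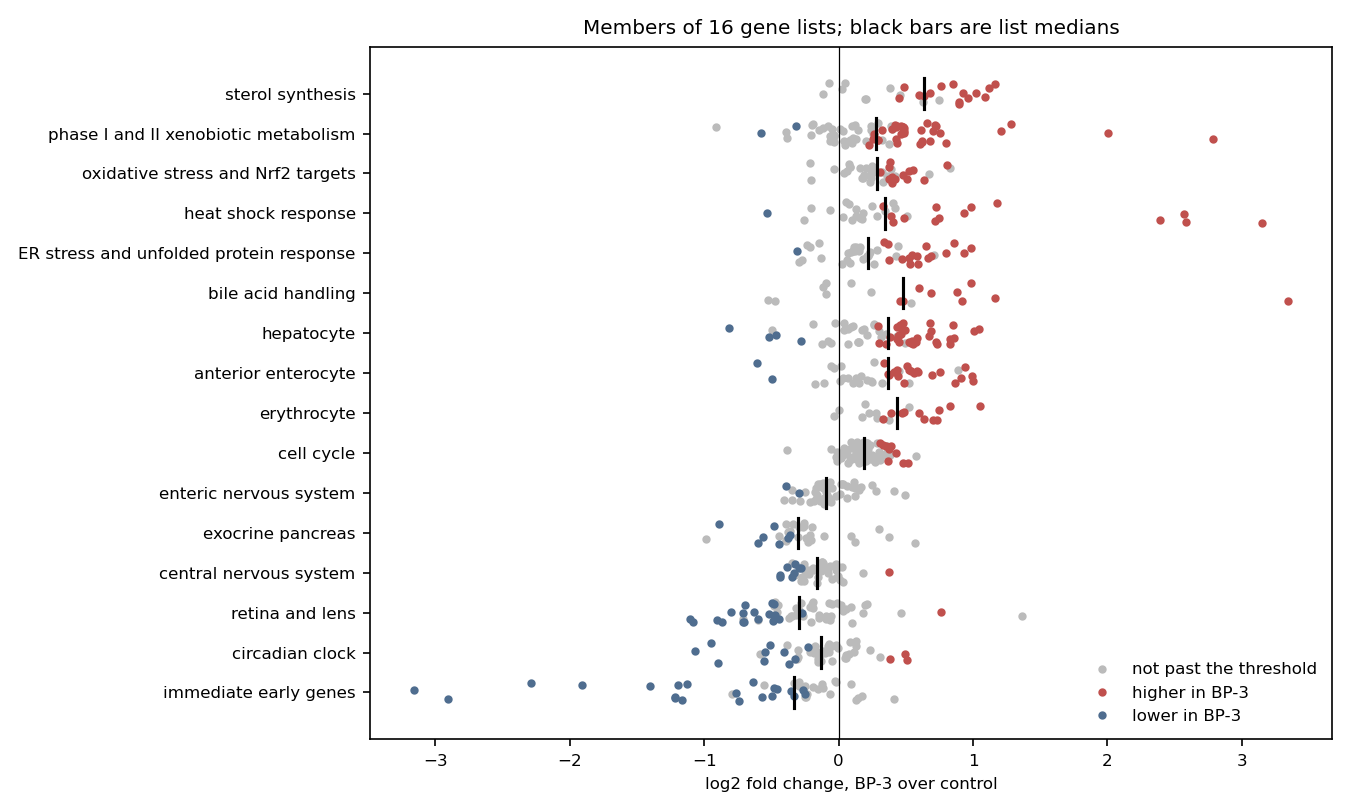
Log2 fold changes, BP-3 over control, of the tested members of 16 gene lists; each point is a gene, coloured by its call at an adjusted p of 0.05, and black bars are list medians. Sterol synthesis has a median of 0.63 with 15 genes higher, and the immediate early genes a median of -0.33 with 21 genes lower.

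Of 48 enteric nervous system genes 0 rose and 2 fell, namely syt1a and plp1b (0 and 2 adjusted over the list alone). The list did not pass camera (adjusted p = 0.0856) but passed fry (adjusted p = 0.011), with a median log2 fold change of -0.091. Of the 2 genes that fell, syt1a stands on the central nervous system list too, so its fall cannot be read as enteric. The enteric progenitor genes ret, gfra1a, phox2bb and sox10 had log2 fold changes of -0.16 ± 0.08, -0.11 ± 0.09, -0.25 ± 0.09 and -0.15 ± 0.09 (SE), none past the threshold. Of 13 goblet cell genes 3 rose (3 adjusted over the list alone), led by the mucin gene muc5.2 at 2.76-fold and agr2 at 1.90-fold. The goblet cell list passed fry (adjusted p = 0.00468) and not camera (adjusted p = 0.0513). Of 30 lysosome-rich enterocyte genes 4 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.270), with slc10a2 1.89-fold higher and the endocytic receptor gene cubn 1.47-fold lower. Of 36 enteroendocrine genes 3 rose and 5 fell (3 and 5 adjusted over the list alone), with a median log2 fold change of 0.03 against a test direction of down (camera adjusted p = 0.859). Smooth muscle and interstitial cells of Cajal had 4 of 30 higher and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.00345, and adjusted p = 0.150 with an estimated correlation). Smooth muscle myosin, myh11a, rose 1.35-fold. Of the remaining gut lists, BEST4 and ionocyte-like epithelium had 1 higher and 1 lower of 14 (1 and 1 adjusted over the list alone; camera adjusted p = 0.286). Endocrine pancreas had 1 higher and 1 lower of 14 (1 and 1 adjusted over the list alone; camera adjusted p = 0.126).

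Markers of tissues beyond the gut were abundant in all libraries labelled intestinal. Skeletal muscle genes took 11.9 ± 0.484% of counts and epidermis genes 2.87 ± 0.181% over the 6 libraries (SD, n = 6). Retina and lens genes took 1.69 ± 0.0998% in control and 1.39 ± 0.0706% in BP-3, and anterior enterocyte genes 1.31 ± 0.0419% and 1.85 ± 0.0248% (SD, n = 3). Apart from eye and liver, tissue shares were not tested as a cause. A part played by gut share in the rises of enterocyte, xenobiotic, sterol and bile acid genes therefore cannot be told apart from exposure. Of 57 retina and lens genes 1 rose and 18 fell (4 and 33 adjusted over the list alone; camera adjusted p = 1.89e-08, and adjusted p = 0.270 with an estimated correlation). The lens crystallin gene cryaa was 2.16-fold lower and crybb1l1 1.63-fold lower. Of 31 exocrine pancreas genes 0 rose and 7 fell (0 and 12 adjusted over the list alone). Their list passed camera (adjusted p = 4.27e-05), but not with an estimated correlation (adjusted p = 0.425), and not fry (adjusted p = 0.118). The carboxypeptidase genes cpa1 and cpb1 were 1.85-fold and 1.28-fold lower. Of 46 central nervous system genes 1 rose and 8 fell (1 and 14 adjusted over the list alone; camera adjusted p = 1.49e-05, and adjusted p = 0.0990 with an estimated correlation). Of 67 skeletal muscle genes 3 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.288). Of 32 epidermis genes 0 rose and 5 fell (0 and 7 adjusted over the list alone), with krt93 2.04-fold lower (camera adjusted p = 0.126).

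**Figure D3:**
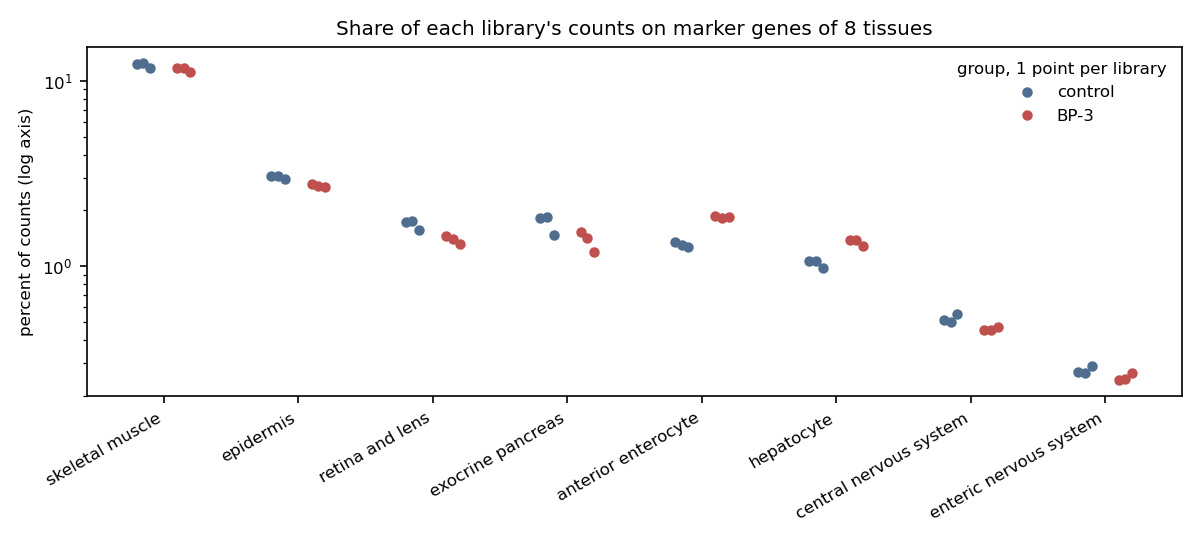
Percent of each library's counts (log axis) on marker genes of 8 tissues, 1 point per library, replicates 1 to 3 from left to right in each group. Skeletal muscle genes lie between 11.2% and 12.5% in the 6 libraries, and anterior enterocyte genes between 1.27% and 1.87%, higher in each BP-3 library than in each control library.

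Of 21 genes of oestrogen response and steroidogenesis 5 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.00685, and adjusted p = 0.150 with an estimated correlation). The brain aromatase gene cyp19a1b rose 2.21-fold from 0.667 ± 0.0805 CPM, and the vitellogenin gene vtg7 rose 7.71-fold from 0.217 ± 0.0281 CPM (SD, n = 3). The vitellogenin gene vtg1 and the receptor gene esr1 had log2 fold changes of 0.59 ± 0.61 and -0.59 ± 0.26 (SE), not past the threshold. In BP-3 and control, vtg1 lay at 0.470 ± 0.355 and 0.315 ± 0.183 CPM, and esr1 at 0.885 ± 0.0597 and 1.34 ± 0.195 CPM (SD, n = 3). Of 15 thyroid axis genes 3 rose (4 adjusted over the list alone), with dio3b at 1.71-fold; its median of -0.03 and its test direction, up, differ in sign (camera adjusted p = 0.447). Of 26 retinoic acid genes 4 rose (4 adjusted over the list alone), led by the carotenoid oxygenase gene bco1l at 2.63-fold. For retinoic acid camera gave adjusted p = 0.0527 and fry adjusted p = 0.0211. Of 74 cell cycle genes 9 rose and 0 fell (11 and 1 adjusted over the list alone; camera adjusted p = 1.41e-07, and adjusted p = 0.213 with an estimated correlation). The mitotic kinase gene aurka rose 1.43-fold and rrm1, of nucleotide synthesis, 1.35-fold. Of 15 histone genes 0 rose and 3 fell (1 higher and 4 lower adjusted over the list alone). Those that fell were the linker histone genes histh1l by 1.95-fold, h1fx by 1.89-fold and h1f0 by 1.63-fold. For histones camera gave adjusted p = 0.0513 and fry adjusted p = 0.0408. Of 20 endothelial genes 3 rose (4 adjusted over the list alone; camera adjusted p = 0.00603, and adjusted p = 0.150 with an estimated correlation). Of 63 targets of Wnt, Notch, Hedgehog, BMP and FGF 2 fell (0 adjusted over the list alone; camera adjusted p = 0.0137, and adjusted p = 0.165 with an estimated correlation). Camera's pass for these targets was lost without BP-3 replicate 2 (adjusted p = 0.0515) and with BP-3 replicate 1 alone (adjusted p = 0.149). Leukocyte genes had 5 higher and 3 lower of 39 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0513). Fibroblast genes had 2 higher and 2 lower of 34 (4 and 4 adjusted over the list alone; camera adjusted p = 0.516). Cartilage and bone genes had 1 higher and 2 lower of 23 (camera adjusted p = 0.318), with a median of -0.05 and a mean of 0.02. Lysosome and autophagy genes had 2 higher and 3 lower of 51 (camera adjusted p = 0.633), with a median of 0.008 against a test direction of down. Of the 80 ribosomal protein genes 0 passed by edgeR and 0 by DESeq2, with 1 at an unadjusted p under 0.05 by edgeR. Camera gave the list adjusted p = 0.129, and adjusted p = 0.814 with its estimated correlation of 0.818. The fits that follow used the preset correlation of 0.01 alone. With the replicate number as a block 7 were lower (camera adjusted p = 0.00806), with the replicate 3 libraries as a batch term 11 were lower (camera adjusted p = 0.00583), and with both of these libraries left out 1 was higher and 3 lower (camera adjusted p = 0.052). Of 13 mitochondrially encoded genes 1 rose (1 adjusted over the list alone). Camera gave them adjusted p = 0.0285, and adjusted p = 0.573 with an estimated correlation, while fry gave adjusted p = 0.273. In the same 3 fits 11, 12 and 6 of the 13 rose and 0 fell, while camera's pass was lost without BP-3 replicate 3 (adjusted p = 0.327), without control replicate 1 (adjusted p = 0.0838), without control replicate 2 (adjusted p = 0.169) and with BP-3 replicate 1 alone (adjusted p = 0.476).

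The replicate 3 libraries of both groups stood apart from the others: mitochondrially encoded genes took 6.93% and 6.07% of counts in BP-3 replicate 3 and control replicate 3, and between 4.80% and 5.51% in the others. The second principal component, with 23.0% of the variance, parted them from the rest. With both left out, chosen after seeing the data, 3894 genes passed, with 2243 of the 2446 among them; with them as a batch term, 5421. Without both, 24 exocrine pancreas genes fell and 1 rose, 18 central nervous system genes fell and 2 rose, and 28 retina and lens genes fell and 3 rose. Further, 19 skeletal muscle genes fell and 6 rose, 12 epidermis genes fell and 3 rose, and 9 enteric nervous system genes fell and 1 rose. In the same fit 20 cell cycle genes rose and 1 fell, and 23 oxidative stress genes rose and 1 fell. Other splits of the 6 libraries gave up to 17 lists past camera with its preset correlation, against 22 for the real groups. The count of 2446 fell to 1242 without BP-3 replicate 1, 1084 without BP-3 replicate 2, 1245 without control replicate 1 and 1287 without control replicate 2, no call changing sign. Taking BP-3 replicate 1 alone, the library whose treatment field reads BP-3, against the controls gave 435 genes.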

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

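The alternatives were chosen before the data were examined, except leaving out both replicate 3 libraries and the batch term, chosen after seeing the data. No gene called over all libraries changed sign in these alternatives, and another scaling moved the median log2 fold change by at most 0.006. The counts of genes were 2440 with DESeq2 size factors, 2444 with the upper quartile, 2266 without a filter, 2560 with 1 CPM in 3 libraries, 2952 with DESeq2 (899 rows without an adjusted p) and 2522 with limma-voom. Of the 166 named genes, 94 kept their side of the threshold in all settings. Some not past the threshold in the main fit passed with the replicate block (2), with the replicate 3 batch term (3) and with both replicate 3 libraries left out (1). Of the 43 lists, 30 did. Among the 22 passing lists, hypoxia response, mitochondrially encoded genes and the Wnt, Notch, Hedgehog, BMP and FGF targets lost camera's pass in at least 1 setting. Camera called ribosomal proteins lower with the replicate block (adjusted p = 0.00806) and the replicate 3 batch term (0.00583), not in the main fit. It also did so without BP-3 replicate 1 (0.000873), BP-3 replicate 2 (0.0499) or control replicate 3 (6.56e-05). With the list's estimated correlation of 0.818 the main fit gave adjusted p = 0.814, so these preset values are too small. Another 9 lists not past the threshold in the main fit passed camera in at least 1 setting. Upward, retinoic acid response passed in 8 settings, goblet cell in 7 and leukocyte in 6, with the smallest adjusted p at 0.0102 (DESeq2), 0.00251 (DESeq2) and 0.0264 (without control replicate 1). Downward, histones passed in 8 settings (smallest adjusted p = 0.000104, DESeq2) and inflammation in 3 (0.000762 with DESeq2, 0.036 with limma-voom and 0.0409 without control replicate 3). Epidermis passed downward with DESeq2 (0.0227) and without control replicate 3 (0.0464), and endocrine pancreas without control replicate 3 (0.0228) and without both replicate 3 libraries (0.0297). The p53 and apoptosis list passed downward with DESeq2 alone (0.0233) and interferon response without both replicate 3 libraries alone (0.0489). The mean log2 fold change of ribosomal proteins was 0.111 with BP-3 replicate 1 alone and -0.05 in the main fit. In that alternative 1 library stands against 3 and the controls alone give the spread, so nothing is read from the change of sign. Leaving out 1 library at a time gave 1084 to 2494 genes, 696 to 1448 higher, 388 to 1046 lower and 226 to 396 list members, with the lowest counts without BP-3 replicate 2. With BP-3 replicate 1 alone the counts were 435 genes, 293 higher, 142 lower, 159 changed at least 2-fold and 137 list members, with fewer libraries. With both replicate 3 libraries left out they were 3894 genes, 1747 lower and 585 list members; with these libraries as a batch term, 5421, 2931 higher, 2490 lower and 711. The cause of these rises was not tested.

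Deviations of same-numbered libraries correlated at 0.086, 0.064 and 0.225, not all above 0.1, so the main fit had no block. BP-3 replicate 3 lay at -0.148 and -0.115 with control replicates 1 and 2, so pairing stays open. The fit with the replicate block called 5026 genes, 2747 higher and 2279 lower, and 681 list members, with all 2446 calls among them. The alternatives for normalized values (another pseudocount, no filter on low values, quantile scaling) could not be applied since the values are counts. In the simulation 53.4% of 1.5-fold changes were called. It held far fewer changed genes than the 2446 called here, which makes the adjusted threshold stricter, so this share does not measure sensitivity in these libraries. Small changes can still be missed, and the part of depth in this was not tested.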

Other observations

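The tests of explanations below were chosen after the results were seen. Beyond the lists, the muscle ubiquitin ligase genes fbxo32 and trim63a fell by 1.53 and 0.93 on the log2 scale in the BP-3 libraries, klhl38b fell by 1.33, and calcoco1b fell by 1.35. The phosphorylase kinase genes phka1b and phkg1a, of glycogen breakdown, rose by 1.43 and 1.54 on the same scale. The stress-responsive muscle gene ankrd1b rose by 1.04 and the small heat shock gene hspb6 by 1.43. Of the actinodin genes, and1 rose by 2.09, while and2 rose by 0.32 and and3 had a log2 fold change of 0.05 ± 0.08 (SE), not past the threshold. Apart from and1, these genes were chosen after their values were seen, and all but and3 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

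Transcripts of eye, skin and muscle in libraries labelled intestinal: 96.0% of 25 photoreceptor genes lay at 10 CPM or more in the control group, and opn1sw1, an opsin gene chosen after its value was seen, reached 1982 CPM. Of the retina and lens list, 1 gene stands on another list. Cells bring all their abundant transcripts, so this is consistent with tissue other than gut in every library, and the share of gut in the RNA was not estimated. Whether whole larvae or a coarse dissection gave these reads was not tested.

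Lower lens and higher liver transcripts: a lower share of eye tissue in the BP-3 libraries would lower photoreceptor genes as well. The median log2 fold change of photoreceptor genes was -0.09 over 25 genes (0 higher and 2 lower) against -0.49 over 29 lens genes (0 higher and 16 lower). A permutation test of genes between the sets gave two-sided p = 2e-05, with genes not independent replicates. The test was chosen after the results were seen, so nothing further is read from it. A lower share of lens tissue alone would give the same difference. A larger share of liver tissue as the whole cause would move genes expressed in liver alone by 1 factor. Of 43 hepatocyte genes on no other list and at 20 CPM or more, however, 55.8% lay over 2 SE from their median, and 2 fell. A normal spread gives about 5%, a rough reference only, as each SE rests on 3 libraries per group. Whether other tissues in these libraries express these genes too was not tested. A change within lens or liver, or a part played by tissue share, stays open, and exposure to BP-3 is the difference that the design names.

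Lower immediate early genes: without both replicate 3 libraries the median log2 fold change of the list was -0.353, so the decrease is present in the other libraries too. Those libraries come from both groups, and a shift they share could not by itself make a difference between groups. The fit was therefore no test of that explanation. Clock genes high around dawn and those high around dusk parted by 0.38 on the log2 scale, but these sets were written after their values were seen, so nothing is read from it. The labels give no times of day, and whether sampling at another time of day plays a part cannot be told. The time from handling to lysis, to which immediate early and hsp70 genes respond, was not tested, as the labels do not give it.

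The 6 libraries split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 2446 genes, 251 changed at least 2-fold and 384 list members, and the highest other splits gave 3, 3 and 0. Each other split mixes BP-3 with control libraries, so the group difference enters the spread and lowers its counts. For lists passing camera with its preset correlation the real split gave 22 and the highest other split 17, in which BP-3 replicates 1 and 2 stood with control replicate 1 and the replicate 3 libraries stood together.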
